A study of Homo sapiens with 6 samples.

How the data were processed

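Libraries were made from poly(A)-selected RNA with a strand-specific kit and sequenced as paired reads of 150 bp, per the labels' protocols. The submitters' processing notes name TopHat2 as a tool and list a mouse and a human genome build. Whether these notes apply to the deposited tables is not given in the sources used here. One deposited table is named for gene reads and the other for FPKM. Neither was used for any measurement.

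The 6 samples were grouped by title into 3 si-NC and 3 si-ALDH18A1 samples before the data were examined. A column of a table was to be given to a sample only where its name matched that sample's title or library name. A match required the shorter of both names, of at least 4 letters or digits, to lie within the other, with case and punctuation ignored; this form of the rule was written after the headers were seen. By this rule, 12 sample columns, 6 in each of the 2 tables, matched no sample and were not used. Column order, the number of columns and the expression values were not used to assign groups. The tests across genes and the gene lists planned for the comparison were not run, so no tool for differential expression was applied.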

Results

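The series describes poly(A)-selected, strand-specific RNA sequencing of HGC-27, an established human gastric cancer cell line. Its labels define 6 samples in 2 groups. The first group holds 3 samples transfected with si-NC, a non-targeting control small interfering RNA. The second holds 3 samples whose titles name small interfering RNA against ALDH18A1. This gene encodes the mitochondrial enzyme that starts proline synthesis from glutamate. The comparison implied by the design is si-ALDH18A1 against si-NC, with the PI3K-Akt signalling pathway named in the series title. The titles of all 3 knockdown samples hold si_ALDH18A1, and those of the 3 control samples hold NC_ALDH18A1. The treatment labels of knockdown replicates 2 and 3 instead name si-ALDH18A2 and si-ALDH18A3. Whether the 3 knockdown samples received the same small interfering RNA was not settled here.

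No expression value of ALDH18A1, of PI3K-Akt pathway genes or of any other gene is reported for these samples. The 2 gene tables of the series, one of read counts and one of FPKM, each carry 6 sample columns, 3 named OE_MEX3A and 3 named OE_NC, each with a replicate number. The OE_MEX3A names hold the symbol of another gene, MEX3A, which encodes an RNA-binding protein, and the OE_NC names hold no gene symbol. Both kinds of name begin with OE, a common abbreviation of overexpression, whereas the labels describe a knockdown. Of the 12 sample columns in both tables, 0 matched the title or library name of a sample of the series. The columns were therefore assigned to neither group, and the comparison of si-ALDH18A1 with si-NC was not analysed here. The effect of the knockdown, its depth per sample and its replicate error are left without a value.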

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

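The comparison of column names was repeated with 3 other rules, all chosen after the headers were seen. Requiring the whole name to be identical gave 0 matching columns, as did requiring the symbol ALDH18A1. Neither count is a separate check. An identical name would already have met the first rule, and the headers already seen lacked that symbol. Counting the shared word NC alone gave 6 columns, 3 in each table. That word names a control in many designs and the rest of those names differs from the labels, so it was not taken as a match. None of the planned processing alternatives was run. No paired analysis was possible because no column name matched a sample of the series; whether the columns hold these libraries under other names was not tested.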
